A study of Mus musculus with 8 samples.

How the data were processed

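CHD4 ChIP-seq was done on dissected, frozen mouse atria, with 4 ChIP libraries and 4 input libraries, per the labels. The cell type is given as mixed. Peak lists of the 4 ChIP libraries were analysed, and the input libraries were not analysed here on their own. Per the series design text, the processed files were made from both ChIP and input reads. The submitters' processing notes name MACS2 and DiffBind, without versions, and the build mm10. The aligner, read filters and call settings are not given in the sources used here. Each deposited list belongs to 1 ChIP library, so replicates were called separately and not pooled.

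The authors' lists give for each peak an interval, a summit and 4 values. The fold of a peak is the authors' ratio of its pileup to the local background. The deposited −log10 p and −log10 q are those of the authors' peak caller, and the lowest −log10 q of a list was 1.30 to 1.31, which corresponds to a q of 0.05. The deposited score equalled 10 times −log10 q without its decimals in at least 99.96% of the peaks of each list. These values served to describe, rank or filter peaks within a list. Comparisons of sites between libraries rest on whether a peak was called. Pileup and background recovered from the values, as given below, were also set side by side between libraries, as estimates. A site not called may still be bound below the threshold, so a list with weaker enrichment loses sites near that threshold. Each difference in depth or enrichment between libraries thus moves the counts of control-only and TBX5 KO-only sites.

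Groups were taken from the titles, library names and peak list names. The genotype and treatment labels of the same samples state the opposite, and the treatment text names CHD4 rather than TBX5 as the deleted gene. The comparison with the groups exchanged is among the alternatives.

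Peaks on chromosomes 1 to 19, X and Y were kept, which were all peaks of the lists, and no interval was listed with several summits. Peaks of the 4 lists were merged into sites where they overlapped by at least 1 bp, and each site took the pattern of libraries in which it was called. A control-only site was called in both control libraries and neither TBX5 KO library. The rank of a site in control was the mean of its percentiles of −log10 p in the control lists, split into 10 deciles. Gene positions came from a RefSeq table of assembly GRCm38.p6, the assembly behind mm10, with 21887 protein-coding genes. That table gives the ends of each gene without strand, exons or introns. Distances to a transcription start were therefore replaced by distances to the nearer end of the gene, and sites are described as within 1 kb of a gene end, inside a gene or outside. Sites were assigned to each protein-coding gene whose body plus 10 kb on each side they overlapped, and 53426 of the sites in both control libraries had at least 1 gene. Of the 247 list genes, 246 were in the table. No genome sequence was used, so the planned search for T-box and 7 other motifs in the sites was not run.

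Peak numbers were compared with a two-sided exact permutation test. Overlaps between lists share libraries and were not tested. Shares of sites were tested with two-sided Fisher's exact tests, with Benjamini-Hochberg adjustment over the 17 gene lists with at least 10 sites. Control rank was matched by permuting control-only status within deciles, with 100000 draws. In a further test the number of control-only sites of a list minus the number expected from their deciles was compared with that of random genes, with 100000 draws. Random genes came from the same one of 20 bins of equal size by number of sites. Genes with the most sites share the top bin with genes of far fewer sites, so p may be too small for lists that hold them. The tests, the gene lists, the groups, the rule for named genes and most alternatives were fixed before the data were examined. The draws of random genes, the mixed patterns in lists of equal length, the expectation by rank and place, the lists without their leading or shared members, and the rule that a list must pass in both same-numbered pairs were added after the data were seen. The alternatives were −log10 q of at least 3 or 5, lists of equal length, an overlap of 50% of the shorter peak or summits within 250 bp, leaving out each library, pairing by replicate number, exchanged groups, 2.5 kb around gene ends, the gene with the nearest end and matching on control rank.

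Named genes were those of the 8 strongest control-only and 4 strongest TBX5 KO-only sites in gene regions, 1 site per gene, up to 3 members of each list with the most control-only sites, and Tbx5, Chd4, Nppa, Nppb, Myl7, Myl2, Sln, Bmp10, Gja5, Ryr2, Gata4 and Nkx2-5. Some genes that the rule takes are not reported here.

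The lists give no read totals. The fold and −log10 p of a peak together fix its pileup and its local background under the Poisson model of the peak caller, taking the fold as pileup plus 1 over background plus 1. A whole-number pileup that met both values to within 0.005 of −log10 p was found for at least 99.98% of the peaks of each library. The background shared by the largest number of peaks of a list was taken as that of the genome. These recovered values are estimates, and only the shares of sites carry Wilson intervals, which cover counting error alone. On simulated data, merging recovered every planted pattern. The simulated sites were spaced so that neighbours could not touch, so merging of wide or neighbouring peaks was not tested. Of 40 simulated lists of 20 genes with a planted odds ratio of 3, 80% were found by permutation within deciles and 85% by random genes at p under 0.05. Of 40 lists with no planted difference, 5% and 7.5% were called. Simulated sites were lost independently of other sites in their gene, so these rates do not cover loss that clusters within genes. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.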

Results

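CHD4 is the ATP-dependent helicase of the NuRD chromatin remodelling complex, and TBX5 is a T-box transcription factor of cardiac development and atrial gene expression. CHD4 occupancy was mapped by ChIP-seq in whole mouse atria. The mice carried floxed Tbx5 alleles and received an AAV9 vector on postnatal day 2. One vector carried Cre recombinase, which excises floxed DNA, and the other carried EGFP as control, both under sequence of Nppa, a gene active in atrial cardiomyocytes. The design compared CHD4 sites in atria with and without TBX5. There were 4 ChIP libraries, 2 titled control and 2 titled TBX5 KO, each with its own list of peaks on build mm10. The groups were taken from the titles. The genotype and treatment labels of the same libraries name the groups the other way round, and no value in a peak list can decide between them, so every direction below rests on the titles. The treatment text also names CHD4 rather than TBX5 as the gene deleted by Cre, in which case a weaker ChIP would mean less of the protein assayed. Tbx5 itself cannot check the labels here, because a CHD4 peak at Tbx5 does not measure Tbx5 expression or deletion. The labels do not say whether the replicates are separate animals or pools, so the spread is that between these libraries and may be technical.

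Fewer CHD4 peaks were called in the libraries titled TBX5 KO. The control lists held 99924 and 91520 peaks, a mean of 95722 ± 5943 (SD, n = 2), and the TBX5 KO lists held 61173 and 69557 peaks, a mean of 65365 ± 5928 (SD, n = 2). The ratio of the means was 1.46, and the ranges of the groups did not overlap. The peaks covered 91.8 ± 7.31 Mb in control and 52.5 ± 6.99 Mb in TBX5 KO atria (SD, n = 2). A two-sided exact permutation test gave p = 0.333, which is the smallest p that 2 libraries against 2 allow, so this design cannot reach 0.05. The lists do not give the number of reads. The background pileup recovered from the peak values was 10.1 and 10.3 in the control libraries and 10.7 and 13.4 in the TBX5 KO libraries, so it was not lower in the libraries with fewer peaks. At the 38027 sites called in all 4 libraries for which a pileup was recovered, the median pileup over this background was 5.76 and 5.41 in control and 3.59 and 3.61 in TBX5 KO libraries.

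Most TBX5 KO peaks lay at control peaks, while many control peaks had no TBX5 KO counterpart. Of the peaks of a TBX5 KO library, between 82.4% and 88.9% overlapped a peak of a control library by at least 1 bp. In the other direction, between 47.4% and 57.8% of the peaks of a control library overlapped a peak of a TBX5 KO library. With each list reduced to its 61173 strongest peaks these shares were 76.9% to 79.3% and 67.2% to 70.2%, so much of the asymmetry went with list length. Replicates overlapped by 73.1% and 81.9% in control and by 78.2% and 66.4% in TBX5 KO atria, depending on which list was counted. The mean overlap was 74.9% within groups and 69.2% between groups, a difference of 5.74 percentage points against an SD of 6.73 among the overlaps within groups. That difference was smaller than this SD. The SD comes from both directions of each replicate pair and, like the difference, depends in part on list length. It therefore cannot tell whether the groups differed.

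Merging the 4 lists gave 121267 sites, of which 68137 were called in both control libraries and 40679 in both TBX5 KO libraries. Of the sites in both control libraries, 38043 were called in all 4 libraries, 13097 in 1 of the TBX5 KO libraries and 16997 in neither. These 16997 control-only sites were 24.9% of the sites in both control libraries (95% Wilson interval 24.6% to 25.3%, counting error only). Only 779 sites were called in both TBX5 KO libraries and in neither control library, which was 1.91% of the sites in both TBX5 KO libraries (1.79% to 2.05%). The 4 patterns of 1 control and 1 TBX5 KO library, which do not follow the groups, held 741 to 2729 sites each. With each list reduced to its 61173 strongest peaks, the control-only pattern held 7090 sites, the TBX5 KO-only pattern 2294 and the mixed patterns 1023 to 1612. In lists of equal length both group patterns therefore held more sites than any mixed pattern, while in the full lists the TBX5 KO-only pattern did not. The control-only count was 30354 without control replicate 1, 37655 without control replicate 2, 21335 without TBX5 KO replicate 1 and 25756 without TBX5 KO replicate 2, since a pattern of fewer libraries is met more often. In the same order the TBX5 KO-only count was 2064, 1351, 6859 and 4703, and it was 3237 by summits and 252 at −log10 q of at least 5.

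**Figure D1:**
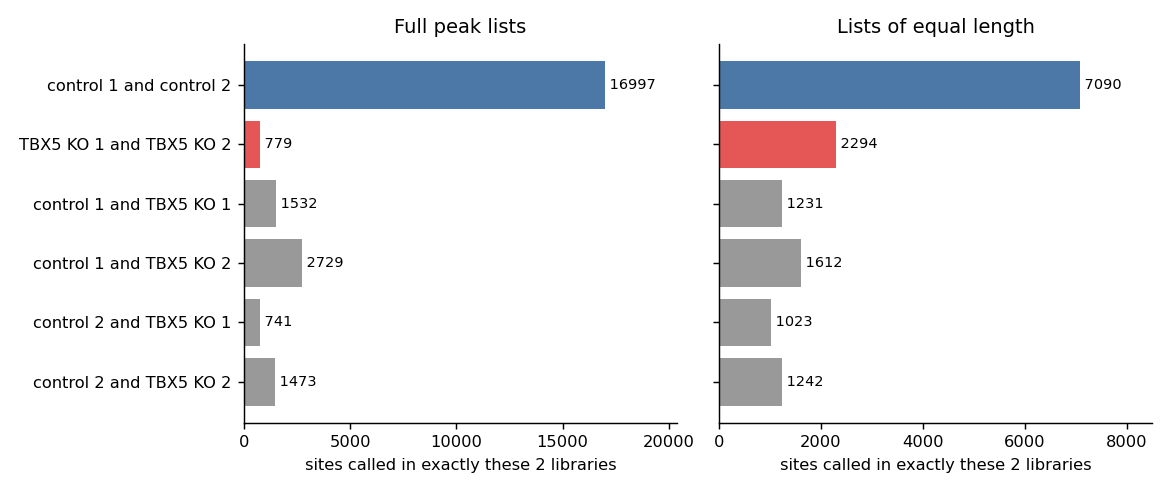
Horizontal bars give the number of merged CHD4 sites called in exactly 2 of the 4 libraries (x axis, sites), for the full lists on the left and for lists of the 61173 strongest peaks on the right, on separate scales. The control-only pattern (blue) held 16997 and 7090 sites, the TBX5 KO-only pattern (red) 779 and 2294, and the mixed patterns (grey) at most 2729 and 1612.

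Control-only sites lay mostly away from the ends of genes, where promoters and transcript ends lie. Of the sites in both control libraries, 7.22% of those within 1 kb of an end of a protein-coding gene were control-only, against 31.1% of those inside genes and 26.6% of those outside genes. In other terms, 5.80% of the control-only sites and 30.7% of the sites called in all 4 libraries lay within 1 kb of a gene end. Of the TBX5 KO-only sites, 65 of 779 (8.34%) lay there, an odds ratio of 0.205 against sites called in all 4 libraries. A low share at gene ends was therefore not particular to control-only sites. The odds ratio was 0.139 by Fisher's exact test (95% interval 0.130 to 0.149, from a normal approximation of its logarithm), or 0.255 with 2.5 kb in place of 1 kb. Weak control sites were control-only far more often than strong ones, with 64.1% in the lowest and 0.426% in the highest decile of control rank. Among sites of matched control rank the odds ratio for gene ends was 0.341 (two-sided permutation test within deciles, p = 1e-05, the smallest that 100000 draws can give). The gene-end shares rest on calls alone. At autosomal gene-end sites of the highest control decile called in all 4 libraries, median TBX5 KO over control pileup over background was 0.521 to 0.602. These gene-end sites that kept their call thus also had lower pileup. Over all sites called in all 4 libraries, of every rank and place, the ratio was 0.629 to 0.683. These sets differ in control rank as well as place, so they cannot tell whether the drop differed at gene ends. Sites are not replicates, and p-values over sites or genes describe these 4 libraries.

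**Figure D2:**
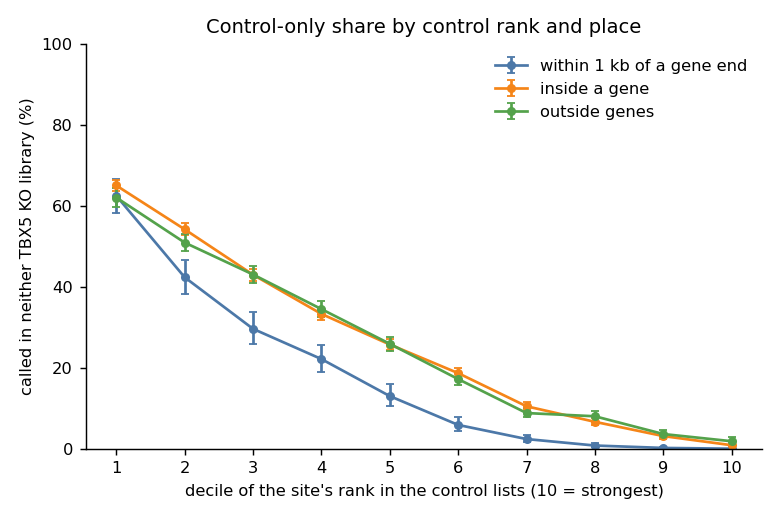
The percentage of sites of both control libraries that were called in neither TBX5 KO library (y axis) is plotted against the decile of the site's rank in the control lists (x axis, 10 is strongest), for sites within 1 kb of a gene end, inside genes and outside genes, with 95% Wilson intervals as bars. The share fell with rank in each place, from 62.5% to 0.0215% at gene ends and from 65.0% to 0.879% inside genes.

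CHD4 sites at genes of the atrial cardiomyocyte programme were called less often in the TBX5 KO libraries than sites at other genes. At the 23 genes of the atrial identity list, 132 of 249 sites (53.0%, Wilson 46.8% to 59.1%) were control-only, against 24.1% of the sites at all other genes. At calcium handling genes the count was 134 of 266 sites (50.4%, 44.4% to 56.3%), and at ion channel and conduction genes it was 80 of 162 sites (49.4%, 41.8% to 57.0%). Fisher's exact test with Benjamini-Hochberg adjustment over the 17 lists gave odds ratios of 3.55 (adjusted p = 2.98e-21), 3.19 (adjusted p = 2.87e-19) and 3.06 (adjusted p = 2.63e-11). Within deciles of control rank the odds ratios were 4.49, 3.14 and 4.59, each with permutation p = 1e-05, the smallest that the draws can give. A permutation test that drew random genes from the same bins of site number gave adjusted p = 0.00085 for atrial identity, 0.00255 for calcium handling and 0.0068 for ion channels and conduction. Genes with many sites, such as Ryr2 and Pam, were drawn against genes with fewer sites there, so these values may be too small. Sites called in all 4 libraries also had a lower pileup over background in the TBX5 KO libraries, as given above.

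Within the atrial identity list, 18 of the 23 genes had at least 1 control-only site. At Fgf12, which encodes a modulator of voltage-gated sodium channels, 14 of 16 sites were control-only, and at Bmp10, which encodes an atrial growth factor of the TGF-beta family, 9 of 11. At Gja5, which encodes the gap junction protein connexin 40 of atrial and conduction cells, 6 of 7 sites were control-only, and at Kcnj3, which encodes a subunit of the acetylcholine-gated potassium channel, 9 of 11. The paired kinase genes Sbk2 and Sbk3 had 5 of 7 and 6 of 9 control-only sites. These neighbouring genes overlap once 10 kb is added on each side, so their counts can include the same sites. Pam, which encodes the enzyme that amidates secreted peptides and is abundant in atrial granules, had the most control-only sites of the list, 31 of 61. Without Pam the share was 53.7%. Kcnj3 was named after its value was seen.

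At 3 atrial genes with few and strong control sites, control rank gave little room for loss. Myl7, which encodes the atrial regulatory myosin light chain, had 1 control-only site of 4, with 0.358 expected from control rank, and the other 3 were called in all 4 libraries. The site at Sln, which encodes the calcium pump regulator sarcolipin, was called in all 4, with 0.0204 control-only sites expected, and the site at Nppa was not control-only, with 0.00426 expected. At Nppa, which encodes atrial natriuretic peptide, a peak of 10050 bp in control 1 (chromosome 4, 147997771 to 148007820) and of 9087 bp in control 2 spanned the gene. TBX5 KO replicate 1 had no peak there, and TBX5 KO replicate 2 had a peak of 373 bp (148000245 to 148000617) with a fold of 1.53 over its local background. That local background was 12.3 times the background of the genome in TBX5 KO replicate 2, and 2.29 and 3.10 times in the control libraries. The neighbouring Nppb, which encodes B-type natriuretic peptide, had a peak in both control libraries and in TBX5 KO replicate 2, with folds of 7.11, 5.94 and 2.5.

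Ryr2, which encodes the calcium release channel of the cardiac sarcoplasmic reticulum, had the most control-only sites of the calcium handling list, 68 of 77. Without Ryr2 the list had 66 control-only sites of 189 (34.9%). The permutation test with random genes, here with sites expected from control rank and place, then gave adjusted p = 0.246. With Ryr2 the same permutation test gave adjusted p = 0.00289, so the call for this list rests on Ryr2 under that test. That test was added after the data were seen. Cacna1c, which encodes the pore of the cardiac L-type calcium channel, had 28 of 64 control-only sites, and Camk2d, which encodes a calcium-dependent kinase, had 9 of 28. Among ion channel genes, Kcnd3, a potassium channel gene, had 10 of 19 control-only sites, and Cacna1d, a calcium channel gene, had 9 of 20. All 17 genes of the ion channel list had at least 1 control-only site. The ion channel list shares 5 genes with the atrial list, and without them 47 of 109 sites were control-only (43.1%, permutation p = 0.00523 with random genes by rank and place, not adjusted, chosen after the data were seen).

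**Figure D3:**
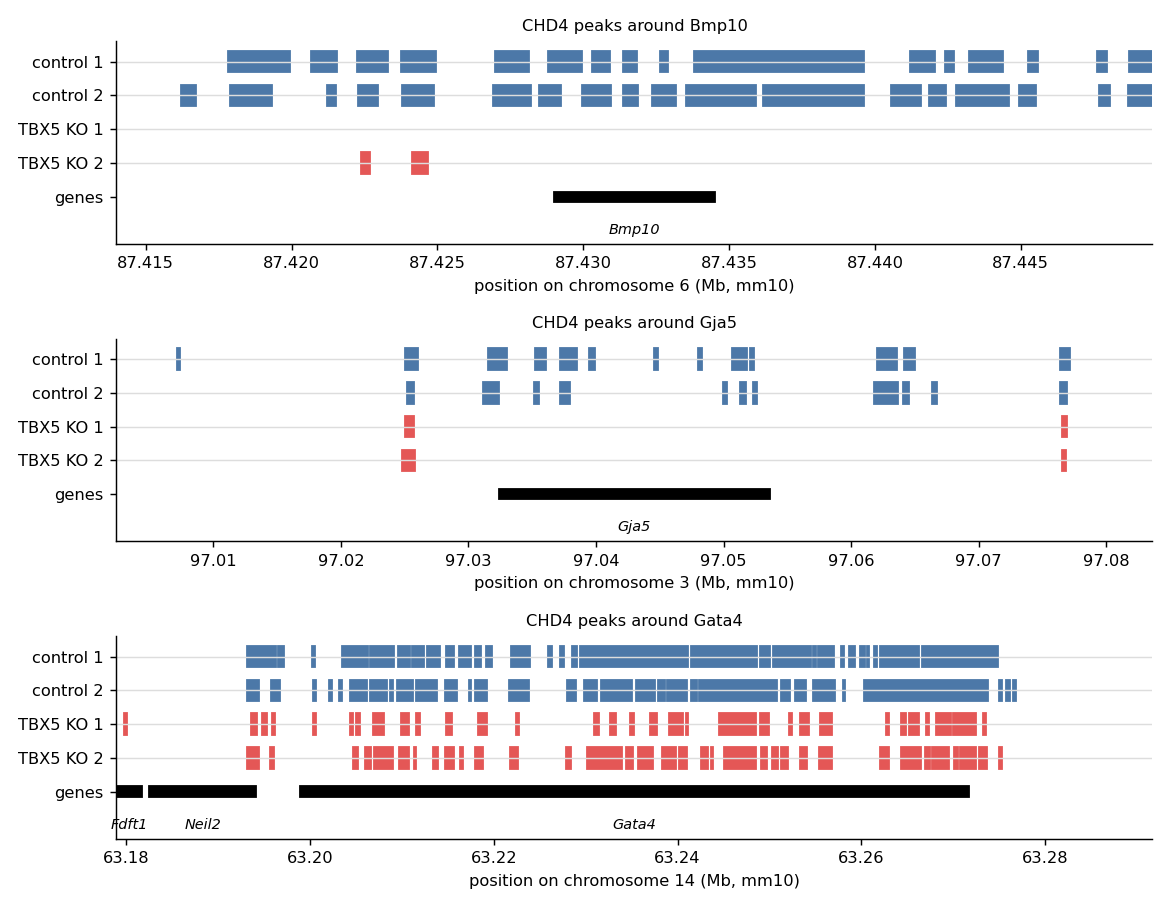
Each panel shows the peaks of the 4 libraries (blue control, red TBX5 KO) and the protein-coding genes (black) along an mm10 region (x axis, Mb) around Bmp10, Gja5 and Gata4, and bar length gives peak length. The region around Bmp10 held 16 and 18 control peaks against 0 and 2 TBX5 KO peaks, while that around Gata4 held 29 and 30 control peaks against 31 and 34 TBX5 KO peaks, which covered 61.0 and 55.8 kb against 26.1 and 36.6 kb.

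Smaller shifts were found in 4 other lists. Sarcomere genes had 63 of 186 control-only sites (33.9%, odds ratio 1.60, Fisher's exact adjusted p = 0.0116) and oxidative metabolism genes 40 of 107 (37.4%, odds ratio 1.87, adjusted p = 0.0116). By the same exact test, cardiac stress genes had 18 of 43 (41.9%, odds ratio 2.25, adjusted p = 0.0311) and neuronal genes 13 of 28 (46.4%, odds ratio 2.71, adjusted p = 0.0311). In the permutation test with random genes the adjusted p was 0.117 for sarcomere, 0.0475 for oxidative metabolism, 0.047 for cardiac stress and 0.0475 for neuronal genes. Within deciles of control rank the adjusted permutation p of the neuronal list was 0.0948. Examples were Actn2, the gene of Z-disc alpha-actinin, and Ttn, the gene of titin. Actn2 had 11 of 26 control-only sites and Ttn 13 of 39, against 9.35 and 10.8 expected from control rank, so both were close to expectation. Ppargc1a, which encodes a coactivator of mitochondrial biogenesis, had 16 of 30, Fabp3, a cardiac fatty acid binding protein gene, 6 of 9, and Hadha, an enzyme gene of mitochondrial fatty acid oxidation, 4 of 7. Myh7, which encodes the beta myosin heavy chain, had 7 of 10, Xirp2, a gene of an actin-binding protein of the intercalated disc, 4 of 4, and Fhl1, a LIM protein gene, 5 of 9. Fhl1 lies on chromosome X, where 36.9% of sites were control-only, against 24.8% on autosomes. Of the neuronal control-only sites, 6 of 7 at Rbfox3, 2 of 2 at Gap43 and 2 of 6 at Syt1 account for most. The calls of all 4 ended without control replicate 1, control replicate 2 or TBX5 KO replicate 1, each of which left 3 lists past the test, and that of cardiac stress genes also without TBX5 KO replicate 2, which left 6. In the test with random genes by rank and place, which sarcomere genes did not pass, the other 3 calls also ended without the member with the most control-only sites. With sites given to the gene with the nearest end, the odds ratio of cardiac stress genes was 1.11 (exact adjusted p = 0.595) and that of neuronal genes 2.30 (exact adjusted p = 0.0905), so both calls ended. By the exact test the cardiac stress call also ended at −log10 q of at least 3 (adjusted p = 0.0519) or 5 (0.0512), with overlap of 50% of the shorter peak (0.0746) and by summits (0.144). Summits also ended the calls of neuronal (exact adjusted p = 0.0856) and oxidative metabolism genes (0.207). Equal length ended that of oxidative metabolism genes (odds ratio 1.91, exact adjusted p = 0.0508). Sarcomere, cardiac stress and neuronal genes kept theirs at equal length, with odds ratios of 1.73, 3.84 and 5.12 (exact adjusted p = 0.0391, 0.0024 and 0.00439).

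CHD4 sites at cardiac transcription factor genes were control-only about as often as sites at other genes, 71 of 273 (26.0%, odds ratio 1.10, Fisher's exact adjusted p = 0.557). At Gata4, which encodes a zinc finger factor of heart development, 1 of 14 sites was control-only and 10 were called in all 4 libraries. Tead1, a gene of a Hippo pathway factor, had 10 of 36 control-only sites, Mef2a, a MADS-box factor gene, 13 of 29, and Esrrg, an orphan nuclear receptor gene, 8 of 18. Nkx2-5, which encodes a cardiac homeobox factor, had 5 of 8. Tbx5 had 7 of 21 control-only sites and 10 sites in all 4 libraries, and Chd4 had 3 of 8 and 4.

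The other 9 lists did not pass the test, with adjusted p between 0.241 and 0.615 by Fisher's exact test, and 0 lists had a lower share past the threshold. That count was also 0 at an unadjusted p under 0.05, and 0 after adjustment in both permutation tests, where fibroblast genes came nearest (adjusted permutation p = 0.051 within deciles). At −log10 q of at least 5 ventricular identity genes passed (odds ratio 2.34, exact adjusted p = 0.0237) and housekeeping genes had a lower share (0.192, exact adjusted p = 0.00445). A lower share was also called for fibroblast genes without control replicate 2 (0.602, exact adjusted p = 0.0475) and for skeletal muscle genes without TBX5 KO replicate 2 (0.393, exact adjusted p = 0.0401). Ventricular identity genes had 18 of 55 control-only sites (32.7%), with 11 of 25 at Fhl2, a LIM protein gene, and 0 of 4 at Myl2, the gene of the ventricular myosin light chain. NuRD complex genes had 22 of 77 (28.6%), with 5 of 13 at Gatad2a and 3 of 7 at Mbd3. Of the lists for other cell types, immune genes had 8 of 25 (32%), with 3 of 7 at the macrophage gene Cd68, 2 of 4 at Csf1r and 2 of 5 at Mrc1. Smooth muscle genes had 23 of 86 (26.7%), with 9 of 20 at Myocd, 8 of 21 at Cald1 and 4 of 22 at Mylk. Endothelial genes had 23 of 124 (18.5%), with 6 of 18 at Flt1, 4 of 17 at Npr3 and 4 of 20 at Pecam1. Fibroblast genes had 16 of 93 (17.2%), with 6 of 32 at the fibrillin gene Fbn1, 3 of 9 at Ddr2 and 2 of 13 at the decorin gene Dcn. Housekeeping genes had 10 of 62 (16.1%), with 3 of 8 at Ywhaz and 2 of 6 at both Actb and Ppia. Skeletal muscle genes had 6 of 43 (14.0%), with 2 of 4 at Atp2a1, 1 of 5 at Ckm and 1 of 3 at Mylpf. Epicardial genes had 1 of 11 (9.09%), the site being at Wt1.

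**Figure D4:**
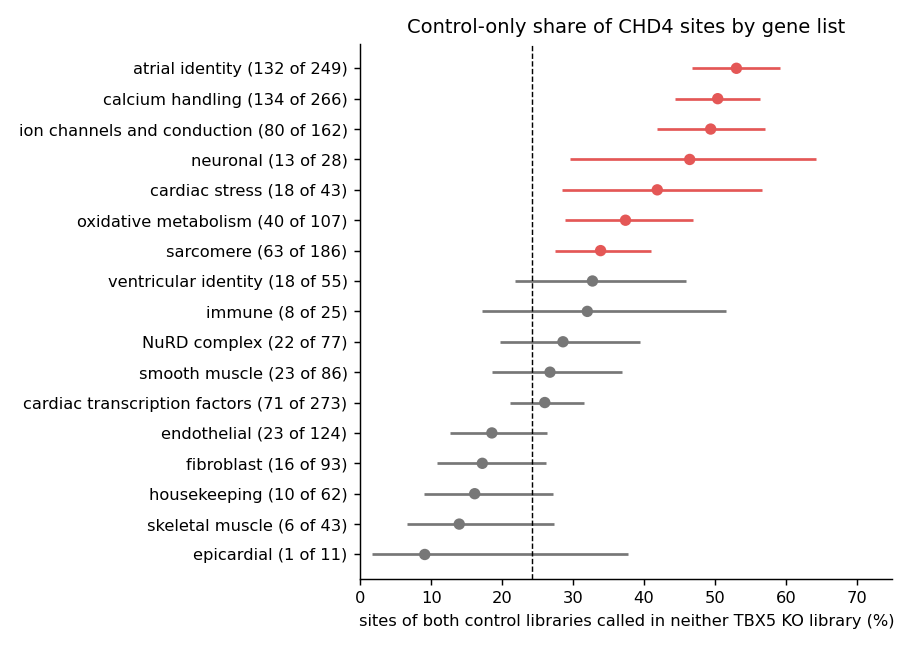
Points give, for each of the 17 gene lists, the percentage of sites of both control libraries called in neither TBX5 KO library (x axis), with 95% Wilson intervals as lines and the counts in the labels. Red marks the 7 lists past an adjusted p of 0.05 by Fisher's exact test, and the dashed line marks the 24.3% of all sites in gene regions.

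The strongest control-only sites lay at genes of atrial muscle and at others. The highest ranked was 1173 bp outside Sbk2 (chromosome 7, 4951733 to 4954961), with folds of 14.8 and 13.3 over local background in the control lists. Next came sites inside Fgf12 (chromosome 16, 28705964 to 28708023; folds of 11.6 and 11.5), Atp11a, a phospholipid flippase gene (chromosome 8, 12832066 to 12835598), and Nav3, a gene of a microtubule-associated protein (chromosome 10, 110399579 to 110401735). The others were inside Rabgap1l (chromosome 1, 160534596 to 160536629), outside Sbk3 (chromosome 7, 4983536 to 4986433), 8163 bp outside Gja5 (chromosome 3, 97061797 to 97063703) and inside Fcamr, a gene of an immunoglobulin receptor (chromosome 1, 130802561 to 130805452). These sites lay at percentiles of −log10 p between 92.9 and 99.3 in the control lists. Around these genes Atp11a had 12 of 17, Nav3 11 of 13, Rabgap1l 8 of 17 and Fcamr 4 of 4 control-only sites.

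TBX5 KO-only sites were fewer. The highest ranked lay inside Sfi1, a centrin-binding protein gene (chromosome 11, 3142441 to 3142808), at percentiles 69.2 and 68.0 of the TBX5 KO lists, with folds of 2.05 and 2.11. Sfi1 held 7 TBX5 KO-only sites, and the median local background of its peaks was 16.2 and 11 times that of the genome in the TBX5 KO libraries and 5.25 and 4.63 times in the control libraries. The next were outside Ehd3, an endocytic protein gene (chromosome 17, 73836398 to 73836864), at an end of Kcnh6, a potassium channel gene (chromosome 11, 106007851 to 106008217), and outside Crb2, a cell polarity gene (chromosome 2, 37768912 to 37769261). The atrial identity, calcium handling and ion channel lists had 0 TBX5 KO-only sites. Fibroblast genes had 0 and endothelial genes had 2.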

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

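The planned tests were chosen before the data were examined. The draws of random genes, their use with rank and place or without a leading member, the mixed patterns in lists of equal length, and the rule that a list must pass in both same-numbered pairs were chosen afterwards. With the groups taken from the genotype and treatment labels, the peak ratio became 0.683, 779 sites were control-only and 16997 TBX5 KO-only, and 0 lists passed. That exchange only swaps the names of the patterns and tests the few sites of the smaller one, so its list values say nothing on the stability of the calls: the odds ratio was 0 for atrial identity, calcium handling, ion channels, oxidative metabolism, NuRD, skeletal muscle and fibroblast, 0.633 for sarcomere, 0.989 for smooth muscle, 1.06 for transcription factors, 1.25 for housekeeping, 1.61 for endothelial, 2.09 for ventricular, 2.69 for cardiac stress, 3.32 for immune and 6.27 for neuronal genes. Pairing by replicate number (block) gave a peak ratio of 1.47, and an exact paired permutation test of 2 pairs cannot go below p = 0.5. Within same-numbered pairs, 52.1% and 42.0% of the control sites were not called in the TBX5 KO library, and the odds ratio for gene ends was 0.200 and 0.184. Of the lists, 3 passed in both pairs (atrial identity, calcium handling and ion channels) and 0 had a lower share in both. The control-only and TBX5 KO-only counts are the same in this pairing by construction. The labels name no day, litter or batch shared by same-numbered libraries, and overlap between groups was 69.2% for same-numbered and 69.2% for other libraries, so it showed no pairing. The peak ratio was 1.38 to 1.56 without single libraries, and the difference in overlap 2.99 to 9.19 percentage points. Control-only sites numbered 7090 in lists of equal length, where the largest mixed pattern held 1612, and 21335 to 37655 without single libraries. TBX5 KO-only sites numbered 252 at −log10 q of at least 5, 2294 in lists of equal length, 3237 by summits and 1351 to 6859 without single libraries. The odds ratio for gene ends stayed below 1 throughout, at 0.0959 to 0.341, with 0.143 to 0.177 without single libraries, 0.255 at 2.5 kb and 0.341 at matched rank. Lists past the exact test numbered 4 by summits and 3 to 6 without single libraries. In the test with random genes by rank and place they numbered 6 with all members and 2 (atrial identity and ion channels) without the leading member. Lists with a lower share numbered 1 at −log10 q of at least 5 and 0 to 1 without single libraries, being housekeeping (0.192), fibroblast without control replicate 2 (0.602) and skeletal muscle without TBX5 KO replicate 2 (0.393). Ventricular genes passed at −log10 q of at least 5 (2.34). Atrial identity and ion channel genes kept their call in all 15 alternatives other than exchanged groups and calcium handling in 14, the exception being the list without Ryr2. Sarcomere and oxidative metabolism genes kept theirs in 8 each, neuronal genes in 7 and cardiac stress genes in 4. Among lists not past the test, the odds ratio crossed 1 for NuRD at −log10 q of 3 (0.903) and 5 (0.470), equal length (0.436), summits (0.989), without single libraries (0.929 to 1.31) and without its leading member (0.910), and for smooth muscle in the same settings of q (0.934 and 0.629), by summits (0.997), without single libraries (0.704 to 1.11), by rank and place (0.999), within pairs (0.867) and without its leading member (0.771). It crossed 1 for immune genes at −log10 q of 5 (0.896), by summits (0.948), within pairs (0.803) and without single libraries (0.888 to 1.15), for transcription factors without single libraries (0.979 to 1.19), matched on rank (0.897), by rank and place (0.844) and without the leading member (0.775), for fibroblast (1.05) and epicardial genes (1.22) by summits, and for housekeeping genes without single libraries (0.549 to 1.001), by rank and place (1.04) and without the leading member (1.10). The causes were not tested. The motif search was not run. The number of reads, and thus which sites lay just under the threshold, is not known.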

Other observations

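Genes outside the lists were ranked, after the data were seen, by control-only sites beyond the number expected from control rank and place, among 1355 genes with at least 10 sites in both control libraries. Camk1d, which encodes a calcium-dependent kinase, led with 25 of 29 control-only sites against 8.37 expected. Corin, which encodes the cardiac protease that cleaves the precursor of atrial natriuretic peptide, had 30 of 40 against 15.6, and Tnni3k, which encodes a cardiomyocyte kinase, 14 of 17 against 5.21. All 16 sites at Tmem163, which encodes a zinc transporter, were control-only, against 4.55 expected. Plekha7, which encodes a protein of adherens junctions, had 18 of 27, Dpf3, which encodes a subunit of the BAF chromatin remodelling complex, 16 of 25, and Rgs6, which encodes a regulator of G protein signalling, 20 of 45. The genes given here and in the next paragraph are examples. Genes that ranked between them are left out, so the examples do not show which kinds of gene led.

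At the other end of this ranking sites were called in the TBX5 KO libraries more often than expected. Nfia and Nfib, which encode nuclear factor I transcription factors, had 10 of 78 and 5 of 43 control-only sites, against 21.1 and 14.2 expected. Foxp1, which encodes a forkhead factor, had 10 of 59 against 18.1. Itga9, which encodes an integrin subunit, had 1 of 41 against 11.7, and Rad51b, which encodes a DNA repair protein, 4 of 61 against 14.3. No test was run on this ranking, since the genes were picked by the value they are ranked on.

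The tests of depth, enrichment, cell share and Nppa background below were chosen only after the results were seen, while the bounds for the chromosome X ratio were set before it was computed. Fewer sites were called in the libraries titled TBX5 KO, and lower depth is argued against by the background pileup, which was above both control values in each TBX5 KO library and on average 1.18 times that in control libraries. Weaker enrichment at all sites may account for much of this: at sites called in all 4 libraries the pileup over background was 0.657 of that in control libraries (median over the 4 pairs of libraries), while replicates differed by factors of 0.932 and 1.003, and that value excludes none of a less efficient immunoprecipitation, lower CHD4 binding after loss of TBX5, and loss of CHD4 itself, which the treatment text names as deleted. Weaker enrichment everywhere does not by itself account for the concentration at atrial identity genes, because at matched control rank and place their odds ratio of control-only status was 4.30 (permutation p = 5e-05 against random genes), an excess not particular to that list, with 4.43 at ion channel and 2.84 at calcium handling genes. A smaller share of cardiomyocytes would lower calls in each list of their genes, and the control-only share beyond expectation was 24.4 percentage points at atrial identity genes, 15.6 above sarcomere genes (permutation p = 0.0162, genes exchanged between the lists), but 3.68 above ion channel genes without the 5 shared ones (p = 0.705) and 0.0126 above them with all members, and 6.44 above calcium handling genes without the 1 shared gene (p = 0.603), or 17.7 without Ryr2 as well (p = 0.0203), while cardiac transcription factor genes had an odds ratio of 0.844. Lists of other cell types had odds ratios of 0.280 (epicardial), 0.496 (fibroblast), 0.586 (endothelial), 0.999 (smooth muscle), 1.49 (immune) and 3.02 (neuronal). Shares differed between the 6 lists (permutation p = 0.0122, 0.0357 without the leading member of each, and 0.0105 to 0.0206 without any 1 of the 5 lists other than neuronal). Without the 28 sites of the neuronal list the permutation p was 0.174. The rule first set took such a difference as against cell share, on the premise that these lists would move alike. A demand added after these first values were seen, that no single list carry the difference, left cell share open. That premise need not hold, since other cell types can change separately, so the difference cannot decide on cell share. The epicardial, fibroblast and endothelial lists lay below 1, as a smaller share of cardiomyocytes could also give, while the immune and neuronal lists lay above 1. A dependence of CHD4 on TBX5 also stays open, untested and resting on the titles.

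The Nppa peak of TBX5 KO replicate 2 was weak although its recovered pileup was 253, against 251 and 231 in the control libraries. The background of the genome was 13.4 in TBX5 KO replicate 2 and 10.1 and 10.3 in control, so these pileups are not on the same scale. The local background of the Nppa peak of TBX5 KO replicate 2 was 12.3 times that of the genome, against 2.29 and 3.10 times in control. At Nppb in TBX5 KO replicate 2 it equalled that of the genome. Only 10 peaks of that library, this one included, had a background as high, and 6 of them lay inside Sfi1. A candidate explanation is extra copies of Nppa sequence from the vector in the DNA, which would raise the background at Nppa and not at Nppb. The control vector carried Nppa sequence too, so the number of copies would have to differ between libraries, which was not measured. The labels give no vector sequence or dose, TBX5 KO replicate 1 has no peak there to measure, and loss of CHD4 at Nppa with TBX5 stays open as untested.

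Chromosome X was looked at after the data were seen. There, 298 of 807 sites in both control libraries were control-only (36.9%, Wilson 33.7% to 40.3%), against 24.8% on autosomes, and the odds ratio at matched rank and place was 3.38. Fewer X copies in the TBX5 KO animals, as from more males, would lower the pileup on X, and the bounds were an X to autosome ratio at least 10% below 1 in all 4 pairs of libraries for this and within 5% of 1 or above in all 4 against it. The ratio of TBX5 KO over control pileup at the strongest gene-end sites was 0.957, 0.940, 0.907 and 0.899 in the 4 pairs, a mean of 0.926 over 29 X sites, which met neither bound. Chromosome Y held 3 and 2 peaks in the control lists and 2 and 1 in the TBX5 KO lists, too few to tell the share of males. The labels do not give the sex of the animals, so the cause stays open.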
